A study of Mus musculus with 20 samples.

How the data were processed

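The data are peak lists of chromatin immunoprecipitation and sequencing libraries from mouse embryos at embryonic day 13.5. Per the labels, NKX2-1 and LHX6 came from wild-type CD-1 basal ganglia, and H3K27ac, H3K4me1, H3K4me3 and H3K27me3 from C57BL/6 MGE, wild type or conditional Nkx2-1 knockout. Samples were grouped by antibody and genotype. Peak lists of 10 libraries were used, 2 for factors and 8 for marks. The 10 input and IgG libraries have no peak list and were not analysed here.

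Per the labels' processing notes, the authors used CASAVA 1.8.2, bcl2fastq 1.8.4, BWA 0.6.2 and MACS2 2.1.0 on build mm9 (NCBIM37). Per the file headers, peaks were called with MACS version 2.1.0.20140616 against input at a p-value of 1.0e-05, without local background or fragment model, with tags extended to 250 bases, 1 tag kept per position and summits split. Per the file headers, H3K4me3 had its own input and the other marks of a genotype shared 1. The authors' columns are the pileup (a signal, in extended tags at the summit), the deposited −log10 p-value and −log10 q-value, and the authors' fold enrichment, a ratio of ChIP to control. The headers state that q-values were not calculated although the column is filled, so it was not used. Single regions were ranked by fold and −log10 p only within a list. Mean folds of the genotypes are printed side by side, and 1 stricter limit of −log10 p was applied to every list. Depth per sample is the authors' count of ChIP tags after removal of duplicates, per the file headers, from 26.8 to 89.1 M.

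Summits with the same start and end were merged into 1 region with the values of its strongest summit. Chromosomes 1 to 19 and X were kept and other contigs left out. Lengths, overlaps (at least 1 base) and distances were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and bedtools 2.31.1, and figures with matplotlib 3.10.9. Genes and TSSs came from GENCODE vM1 on NCBIM37 (22342 protein-coding genes, 45939 TSSs). Coordinates are counted from 1 on NCBIM37. Intervals on shares are exact 95% Clopper-Pearson intervals and cover counting error only.

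Factor peaks were set beside 100 random placements on the same chromosome, and the shared peaks also beside 1000 draws of wild-type H3K27ac or H3K4me1 regions. For losses and gains, regions holding a factor peak were set beside 10000 lists of regions of the same mark without the peak, matched on the decile of −log10 p, the tercile of length and the presence of H3K4me3 (H3K27me3 for H3K4me3). A value outside the central 95% of the matched lists was called. With 1 library per group no p-value between genotypes can be given, and such a call describes these libraries only. Distal NKX2-1 peaks, here those without H3K4me3 in either genotype, were put into 5 states by H3K27ac, H3K4me1 and H3K27me3. Motif cores were counted on both strands in 200 bases around the summit.

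The 14 gene lists were fixed before the data were examined: MGE and ventral telencephalic transcription factors, LGE and CGE identity, cortical interneurons, cholinergic projection neurons, SHH pathway, progenitors and cell cycle, WNT and BMP pathways, pallial neurons, oligodendrocyte lineage, endothelium with mural cells and blood, microglia, NKX2-1 targets in lung and thyroid, Hox genes and housekeeping genes. Of 250 entries 246 matched the annotation, 1 was an older symbol of a gene already listed, and Slc18a3, Disp1 and Sox1 had no match. Matched lists of genes shared the decile of H3K27ac regions within 50 kb. Named peaks and promoters followed a rule fixed at the same time: the 12 strongest peaks of each factor and of the shared peaks, the 8 strongest regions of each kind of change at NKX2-1 peaks, and up to 8 promoter changes per list. Results for some genes are not reported here.

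Added after the data were seen were the peaks found in all 10 lists, the coverage of each mark within 10 kb of each gene's TSSs with its 1% tails, the stretch around Nkx2-1, motif shares by class of peak, the copies in the reference of the 32-base words at summits and the regions lost at LHX6 peaks. Coverage windows ran from 10 kb before a gene's first TSS to 10 kb after its last, with everything between. For coverage, lists were matched on the decile of the larger coverage of the genotypes.

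The matched lists were tested on simulated losses of H3K27ac, with 200 simulations per setting. With no added loss, 1.5% of simulations with 800 regions and 6.5% with 4000 were called. With 5 percentage points added, 98% and 100% were called, with mean differences of 5.09 and 4.96 points. The simulated losses were independent and set by the decile of −log10 p, which is also matched. These rates therefore do not cover losses that cluster or depend on unmatched traits. Covered bases in 300 windows, copies of 169 words and 18 overlap counts against bedtools gave 0 mismatches.

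Alternatives fixed beforehand were a larger overlap, a distance of 1 kb, −log10 p of at least 10, fold of at least 4, both genotypes at the same covered length, matching without H3K4me3, distal or merged regions, and other windows for genes and motifs. Added later were autosomes alone, finer matching, peaks in all 10 lists left out, windows of 25 kb, Nkx2-1 left out of its list, and genes of other cell types counted only where acetylated.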

Results

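The series profiled 2 transcription factors and 4 histone marks by chromatin immunoprecipitation and sequencing in the mouse forebrain at embryonic day 13.5. NKX2-1 and LHX6, homeodomain factors of the medial ganglionic eminence (MGE), were precipitated from wild-type basal ganglia. H3K27ac (active promoters and enhancers), H3K4me1 (enhancers), H3K4me3 (promoters) and H3K27me3 (Polycomb repression) were precipitated from MGE tissue of wild-type embryos and of embryos with a conditional knockout of Nkx2-1, called the mutant here. Of 20 libraries, the 10 with a peak list were used. Each antibody and genotype has 1 library, so no value has a replicate error and every difference between genotypes describes these libraries.

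After removal of duplicates by the authors' peak caller, the NKX2-1 library held 89.1 M tags (M, mega) and the LHX6 library 50.7 M. The wild-type libraries held 57.3 M tags for H3K27ac, 59.7 for H3K4me1, 28.8 for H3K4me3 and 50.2 for H3K27me3. The mutant libraries held 55.9, 69, 26.8 and 46.7 M in the same order. Duplicates made up 28.3% of the wild-type and 34% of the mutant H3K4me3 tags and at most 6.96% in the other lists. On chromosomes 1 to 19 and X the lists held 5683 NKX2-1 peaks and 1651 LHX6 peaks. H3K27ac had 62591 regions in wild type and 67387 in the mutant, H3K4me1 99089 and 107694, H3K4me3 34661 and 43648, and H3K27me3 21252 and 28077.

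At the targeted gene the mutant lacked every mark over 1 stretch. In the mutant no region of any of the 4 marks lay between 57630281 and 57634772 on chromosome 12, a stretch of 4492 bases that holds the last exon of Nkx2-1, the gene that specifies the MGE (exon at 57632922 to 57634767, minus strand). In wild type H3K4me3 covered 100% of this stretch, H3K27ac 98.1%, H3K27me3 86.2% and H3K4me1 44.1%. Among 118919 stretches between mutant regions, this was the 1 with as much wild-type coverage of all 4 marks, and the 1 with as much H3K4me3. Right beside it the marks remained. Within 10 kb of the transcription start site (TSS) but outside the stretch, Nkx2-1 had 8.18 kb of H3K27ac in wild type and 9.56 kb in the mutant, 117% of the wild-type length, and H3K4me3 covered 7.80 and 10.2 kb. The H3K27ac region over the TSS had a fold enrichment of 15.7 in the wild-type list, above 99.3% of its regions, and 19 in the mutant list, above 99.8%. This locus was examined after its values were seen, and whether the stretch is the segment deleted in the mutant was not tested.

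**Figure D1:**
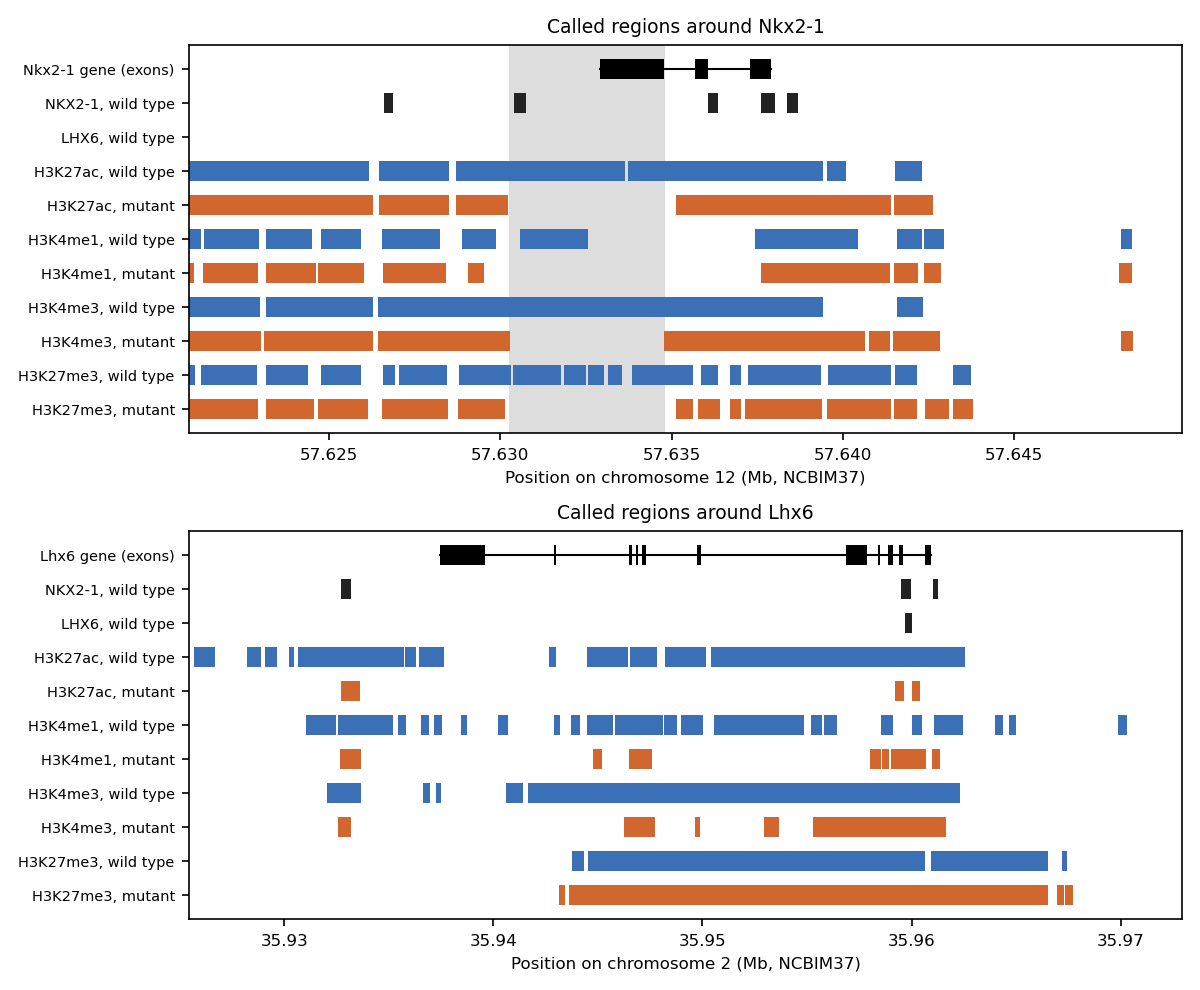
Called regions around Nkx2-1 (chromosome 12) and Lhx6 (chromosome 2), in Mb of build NCBIM37, with exons in black, wild-type mark regions in blue and mutant ones in orange, 1 library each. The grey stretch over the last exon of Nkx2-1 (57630281 to 57634772) has no mutant region of any mark, and the H3K27ac regions over Lhx6 shrink to 2 short ones in the mutant.

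Lhx6 and Lhx8, which encode the LIM homeodomain factors of MGE-derived interneurons and cholinergic neurons, lost most of their acetylation. H3K27ac covered 70.9% of Lhx6 with 2.5 kb on each side in wild type and 2.74% in the mutant, H3K4me1 56.2% and 15.4%, and H3K4me3 77.8% and 30.8%, while H3K27me3 covered 67.4% and 70.4%. At Lhx8, H3K27ac covered 22.5% and 3.78% and H3K4me3 41.6% and 21.4%. In these windows lay 2 NKX2-1 peaks and 1 LHX6 peak at Lhx6, and no peak of either factor at Lhx8.

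Which genes differ in marks between genotypes was asked for all 22342 protein-coding genes, by the length each mark covered around the gene. The window ran from 10 kb before the first TSS to 10 kb after the last, with everything between. It is called within 10 kb of the TSSs here. Changes were ranked in kb, so genes with TSSs far apart had longer windows in which to change. For Tcf4 the window ran from 69493800 to 69763080 on chromosome 18. The 223 genes with the strongest fall and the 223 with the strongest rise of each mark (1% tails) were compared with fixed gene lists, beside 10000 lists of genes matched on coverage. This measure was chosen after the peak lists were seen. The tails began at changes of −1.58 and 2.81 kb for H3K27ac and −1.56 and 2.63 kb for H3K4me1. For H3K4me3 they began at −0.354 and 2.72 kb, and for H3K27me3 at −0.4 and 2.82 kb. A gene in the lower tail of the last 2 marks may thus have changed little. Over all genes the mutant covered 1.08 times the wild-type length of H3K27ac, 1.03 times that of H3K4me1, 1.13 of H3K4me3 and 1.22 of H3K27me3.

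MGE and ventral telencephalic transcription factors were over-represented among the genes that fell. H3K27ac was in the lower tail at 8 of 34 (matched median 2, upper bound 5), namely Lhx6, Lhx8, Sox6, Tcf12, Satb1, Zic1, Sp9 and Nkx2-1. Lhx6 fell from 12.8 to 0.781 kb, Lhx8 from 9.99 to 1.11 kb and Sox6, which acts downstream of Lhx6 in interneurons, from 17.9 to 12.9 kb. Without Nkx2-1, whose fall lies inside the unmarked stretch, 7 of 33 remained against an upper bound of 4. H3K4me3 was in the lower tail at 12 genes (median 1, upper bound 3). Gbx1 fell from 6.52 to 1.96 kb and Gbx2 from 8.99 to 6.04 kb, both homeobox genes. Some of the 12 fell little, such as Dlx1 from 19.1 to 18.6 kb and Tcf12 from 11.5 to 10.9 kb. H3K4me1 was in the lower tail at 6 genes (median 2, upper bound 5), and at 5, inside the range, without Nkx2-1; it was also inside within 25 kb and at the same covered length. H3K27me3 was in the higher tail at 8 genes (median 3, upper bound 6). Sox6 rose from 8.57 to 15.3 kb, Lmo3 from 1.33 to 7.61 kb and Maf, a regulator of interneuron fate, from 2.38 to 6.25 kb, and Gsx2, Nkx2-4, Etv5 and Dlx6 were in this tail as well. Six3, a forebrain homeobox gene, went against the list, with H3K27ac rising from 14.4 to 18.4 kb and H3K4me3 from 15.8 to 20.5 kb, as did Nkx2-2 in H3K4me3 (from 3.80 to 7.90 kb) and Zeb2, whose H3K27me3 fell from 2.22 to 1.30 kb. Summed over the list, H3K27ac covered 281 kb in wild type and 253 kb in the mutant.

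Genes of the neighbouring lateral and caudal ganglionic eminences (LGE and CGE) were over-represented among the genes that rose. H3K27ac was in the higher tail at 12 of 26 (median 1, upper bound 4). Meis2, a homeobox gene of the striatal lineage, rose from 33.2 to 53.9 kb. Foxp1, a forkhead gene of striatal neurons, rose from 5.95 to 15.9 kb, Isl1, a LIM homeobox gene of striatal and cholinergic neurons, from 5.28 to 12.7 kb, Zfp503 from 5.82 to 13.4 kb, Tle4 from 3.47 to 10.2 kb and Ebf1, a factor of differentiating striatal neurons, from 0.251 to 6.83 kb. Foxp2, Rarb, Nr2f1, Nr2f2, Pax6 and Zfhx3 completed the 12. H3K4me3 was in the higher tail at 10 genes (median 2, upper bound 4) and H3K4me1 at 7 (median 1, upper bound 4). H3K27me3 was in the lower tail at 4 (median 1, upper bound 3): Tle4 fell from 15.5 to 8.50 kb, Zfhx3 from 13 to 6.09 kb, Meis2 from 14.4 to 7.84 kb and Zfp503 from 18.6 to 15.9 kb. This count fell inside the range with finer matching. Htr3a, a serotonin receptor gene of CGE interneurons, went against its list, with H3K27ac falling from 4.20 to 1.83 kb, and Sp8, a zinc finger gene, fell in H3K4me1 from 4.49 to 2.79 kb. Rarb, Prox1 and Tshz1 were in the higher tail of H3K27me3, inside the matched range as a count. The list's H3K27ac summed to 147 kb in wild type and 238 kb in the mutant, 1.63 times as much.

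**Figure D2:**
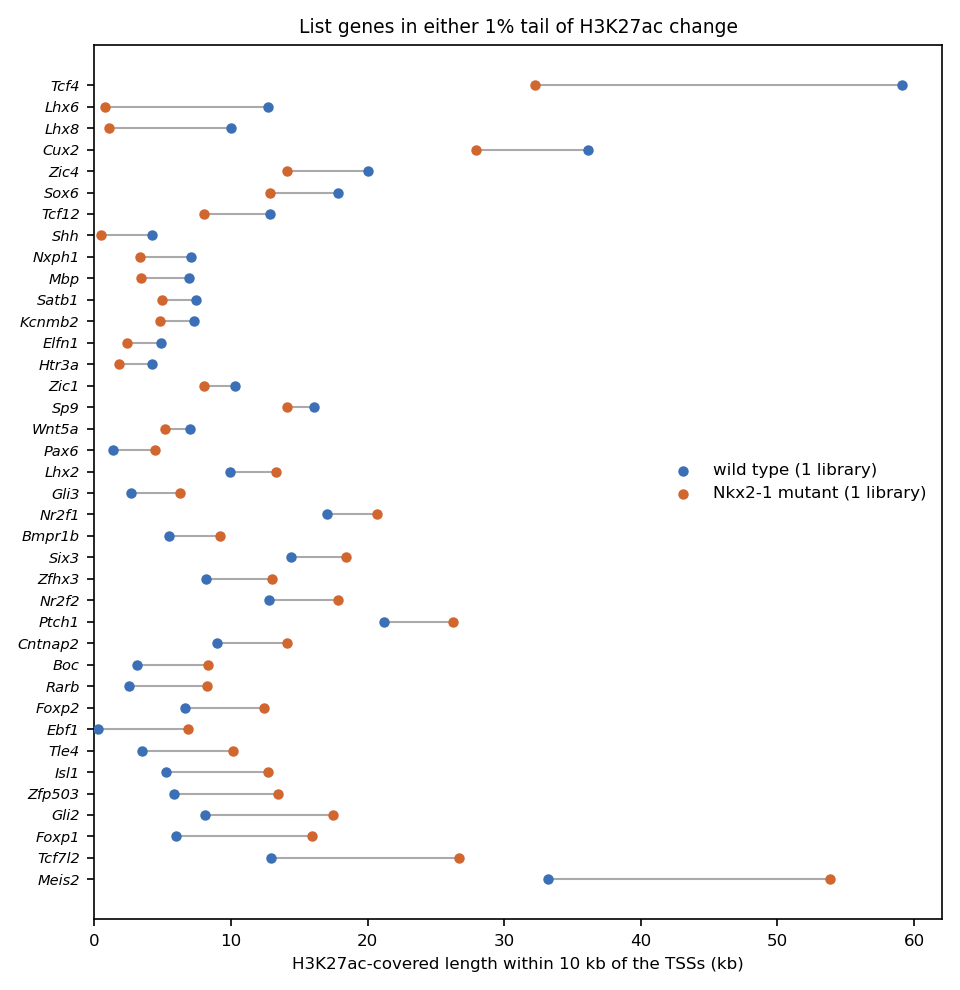
H3K27ac-covered length (kb) from 10 kb before a gene's first TSS to 10 kb after its last. Wild type is blue and the mutant orange, 1 library each. Shown are the genes of the fixed lists in either 1% tail, without Nkx2-1. Tcf4, Lhx6 and Lhx8 head the falls, and Meis2, which rose from 33.2 to 53.9 kb, ends the rises.

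Part of the interneuron genes fell with the MGE list, with which they share genes such as Maf, Sox6 and Satb1. H3K27ac was in the lower tail at 7 of 30 (median 1, upper bound 4). Tcf4, a basic helix-loop-helix partner factor, fell from 59.1 to 32.3 kb, the strongest fall of any gene, and Cux2 from 36.1 to 27.9 kb. Nxph1, Kcnmb2 and Elfn1, genes of synaptic and channel proteins, were the others outside the shared genes. H3K4me3 was in the lower tail at 12 genes (median 1, upper bound 3). Among them were the neuropeptide gene Npy, from 4.58 to 1.94 kb, and the potassium channel gene Kcnc2, from 4.44 to 2.82 kb. Some of the 12 fell little, such as Epha5 from 6.14 to 5.66 kb. Cntnap2, a neuronal adhesion gene, rose in all 4 marks, in H3K27ac from 8.97 to 14.1 kb, in H3K4me1 from 11.8 to 15.3 kb in H3K4me3 from 7.67 to 11.2 kb and in H3K27me3 from 1.71 to 6.11 kb, and Robo1, an axon guidance receptor gene, rose in H3K4me3 from 5.27 to 8.33 kb. Of 11 cholinergic neuron genes, 4 are in the MGE list and Isl1 in the LGE list. Lhx8, Zic1 and Zic4 were in the lower tail of H3K27ac (3 genes, median 0, upper bound 2). The lower tail of H3K4me1 also held 3 (median 0, upper bound 2), inside the range within 25 kb of the TSSs. That of H3K4me3 held 5 (median 0, upper bound 2), Zic1 and Zic4 among them. The Zic1 window lies inside that of Zic4, so the same regions count for both genes. Taken as 1 locus, they would leave the H3K27ac count within its upper bound.

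In the SHH pathway, Shh, the ventral morphogen, had 4.20 kb of H3K27ac in wild type and 0.498 kb in the mutant, in the lower tail. Other pathway genes rose, with H3K27ac in the higher tail at 4 of 13 (median 0, upper bound 2): Gli2 from 8.08 to 17.5 kb, Boc from 3.15 to 8.33 kb, Ptch1 from 21.2 to 26.3 kb and Gli3 from 2.66 to 6.28 kb. H3K4me1 was in the higher tail at 4 genes (median 1, upper bound 2) and H3K4me3 at 3 (median 0, upper bound 2), the latter inside the range at the same covered length. H3K27me3 was in the lower tail at 3 (median 0, upper bound 2): Gli2 fell from 24.3 to 3.96 kb, the strongest fall of any gene, Boc from 10.3 to 1.36 kb and Gas1, a co-receptor gene, from 8.48 to 6.49 kb. Ptch1 (from 1.86 to 5.62 kb) and Hhip (from 2.27 to 7.55 kb), which bind SHH, were in the higher tail of H3K27me3.

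The other lists stayed inside their matched ranges, apart from H3K4me3 at pallial neuron genes, in the higher tail at 3 of 16 (median 1, upper bound 2), namely Fezf2, Lhx9 and Lhx2. In the higher tail of H3K27ac were 2 of 20 WNT and BMP genes (Tcf7l2, from 13 to 26.7 kb, and Bmpr1b), 1 of 16 pallial genes (Lhx2) and 0 of 20 progenitor, 8 oligodendrocyte, 12 endothelial and blood, 6 microglial, 12 lung and thyroid, 22 Hox and 16 housekeeping genes. In its lower tail were 1 WNT and BMP gene (Wnt5a), 1 oligodendrocyte gene (Mbp) and 0 of the rest of these lists.

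Genes whose H3K27ac fell lay near NKX2-1 peaks more often than matched genes, and genes of both tails lay near LHX6 peaks more often. An NKX2-1 peak lay within 50 kb of a TSS at 69.1% of the 223 genes in the lower tail (154 genes; matched median 54.7%, central 95% 48.4 to 61.0), and at 50.2% of those in the higher tail (median 61.9%, 57.0 to 67.3). For LHX6 the shares were 23.8% in the lower tail (median 8.52%, 5.38 to 11.7) and 17.0% in the higher tail (median 13%, 9.42 to 16.1). Over all genes they were 26.96% for NKX2-1 and 2.766% for LHX6, below both tails. Both factors were called in wild type, and genes were matched on the larger coverage of the genotypes. Genes that fell thus tend to have more wild-type H3K27ac than their matched genes, and genes that rose less. This by itself favours peaks near genes that fell, so the contrast between the tails cannot decide whether binding plays a part.

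Where NKX2-1 and LHX6 bind was asked in wild type. Of NKX2-1 peaks, 26.8% lay within 2.5 kb of a TSS (95% interval 25.7 to 28), 29.7% in introns and 41.3% between genes. LHX6 peaks lay less often close to a TSS, with 6.54% within 2.5 kb (5.40 to 7.84), 32.1% in introns and 59.0% between genes. H3K27ac marked 70.4% of NKX2-1 peaks (69.2 to 71.6; 3.31% after random placement on the same chromosome), H3K4me1 68.5% (placed 4.75%), H3K4me3 61.2% (placed 2.52%) and H3K27me3 8.45% (placed 1.37%). Of LHX6 peaks, 40.3% carried H3K27ac (37.9 to 42.7; placed 3.33%), 44.5% H3K4me1 (placed 4.85%), 32.2% H3K4me3 (placed 2.54%) and 22.7% H3K27me3 (placed 1.33%).

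The summits held the sequences these factors recognise. A core of the NK2 homeodomain family (CACTTGA, CACTCAA or their complements) lay in 21.4% of NKX2-1 summit windows of 200 bases (20.4 to 22.5), against 4.91% of windows 1 kb to the sides and 4.27% of shuffled windows. A LIM homeodomain core (TAATTA or TAATGA) lay in 41.5% of LHX6 windows (39.1 to 43.9), against 17.3% at the sides and 24.6% after shuffling. The LIM core was also raised in NKX2-1 windows (25.7% against 15% at the sides), and the NK2 core in LHX6 windows (8.42% against 5.45%).

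NKX2-1 and LHX6 shared many sites. Of LHX6 peaks, 61.8% (1021; 59.5 to 64.2) overlapped an NKX2-1 peak, against 0.242% after random placement, and 18.2% of NKX2-1 peaks (1034) overlapped an LHX6 peak. Of the 1021 shared LHX6 peaks, 62 lay in all 10 lists. Outside those, 455 carried wild-type H3K27ac or H3K4me1, with the LIM core in 55.8% of their windows. The other 504 carried neither mark, with the LIM core in 22.4%, and what they are is left open below. Among the 801 LHX6 peaks with H3K27ac or H3K4me1 the share was 64.5%, against a median of 5.24% for regions of those marks drawn at random. Outside the peaks found in all 10 lists, the strongest shared peak lay at 42751986 to 42752762 on chromosome 13, 23.8 kb from Phactr1, an actin regulator, and another lay in an intron of Tle1, a Groucho co-repressor gene, at 71843233 to 71843747 on chromosome 4. Among the 12 strongest of these, 2 lay on either side of Lhx6 on chromosome 2, nearest to Ttll11 and Ptgs1, at 35866978 to 35867434 and 36058547 to 36059255, each with H3K27ac in both genotypes and H3K27me3 in the mutant alone. Of the 12 strongest peaks of each factor, 10 NKX2-1 and 12 LHX6 peaks lay in all 10 lists, including those over Sfi1 on chromosome 11.

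The strongest NKX2-1 peaks outside those lay near Phactr1 and Epha4, an axon guidance receptor gene (77528689 to 77529310 on chromosome 1, 17.3 kb away). The peak nearest to Cobl, at 12132328 to 12132822 on chromosome 11, had H3K27ac and H3K4me1 in wild type and no mark in the mutant. The strongest LHX6 peaks outside all 10 lists included 1 in an intron of Galntl6, a glycosyltransferase gene (60850985 to 60851623 on chromosome 8), which had H3K27ac in wild type alone, and 1 in an intron of Qk, an RNA-binding protein gene (10444196 to 10444755 on chromosome 17), with H3K27ac in both genotypes.

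What happens to marks at factor sites in the mutant was asked by counting wild-type regions with a factor peak that no mutant region overlapped (lost) and the reverse (gained), beside 10000 matched lists of regions without the peak. At NKX2-1 sites 10.4% of H3K27ac regions were lost (460 of 4405), above the matched median of 4.81% (central 95% 4.29 to 5.36). H3K4me1 was lost at 9.38% (matched 4.67%, 4.13 to 5.23) and H3K4me3 at 7.43% (2.53%, 2.07 to 3.01), both above, and H3K27me3 at 11.1% (11.9%, 9.22 to 14.6), inside, but above at the same covered length and when regions within 1 kb counted. Away from H3K4me3, 44.8% of H3K27ac regions at NKX2-1 sites were lost (302 of 674; matched 24.6%, 21.7 to 27.6). Over all regions, without matching, 19.4% of H3K27ac, 15.2% of H3K4me1 and 3.65% of H3K4me3 were lost. Over all regions away from H3K4me3, 40.3% of H3K27ac and 27.1% of H3K4me1 were lost, against 44.8% and 30.8% at NKX2-1 sites. With an overlap of at least 50% required, 6.63% of H3K27ac was lost at NKX2-1 sites, 3.38 points above matched lists instead of 5.63. Gains were rarer than in matched lists for all marks: 2.91% for H3K27ac (matched 9.12%, 8.44 to 9.82), 2.36% for H3K4me1 (7.81%), 6.06% for H3K4me3 (16.8%) and 19.6% for H3K27me3 (35.1%). At NKX2-1 sites without an LHX6 peak, the H3K27me3 gains of 27.3% lay inside the range (28.6%, 24.4 to 32.4).

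LHX6 sites lost the active marks as well. H3K27ac was lost at 24.8% (197 of 793; matched 7.82%, 6.18 to 9.46), or 12.3% (matched 5.02%) with an overlap of at least 50%, H3K4me1 at 13.9% (7.56%, 6.12 to 9.24) and H3K4me3 at 19.8% (4.72%, 3.15 to 6.47), while H3K27me3 was lost at 10%, below its matched 13.8% (10.8 to 16.9), a call that turned to above at the same covered length. Gains lay below matched lists for all marks, at 2.91% (matched 17.1%), 5.77% (12.1%), 10.2% (29.8%) and 15.1% (40.5%) in the same order, of which H3K4me3 was inside the range at the same covered length. LHX6 sites with an NKX2-1 peak lost H3K27ac at 18.2% (matched 5.49%, 3.79 to 7.20) and those without at 38.1% (12.7%, 9.33 to 16.4). The difference between these groups was not tested. Both factors were called in wild-type tissue, which by itself favours losses over gains at their sites.

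**Figure D3:**
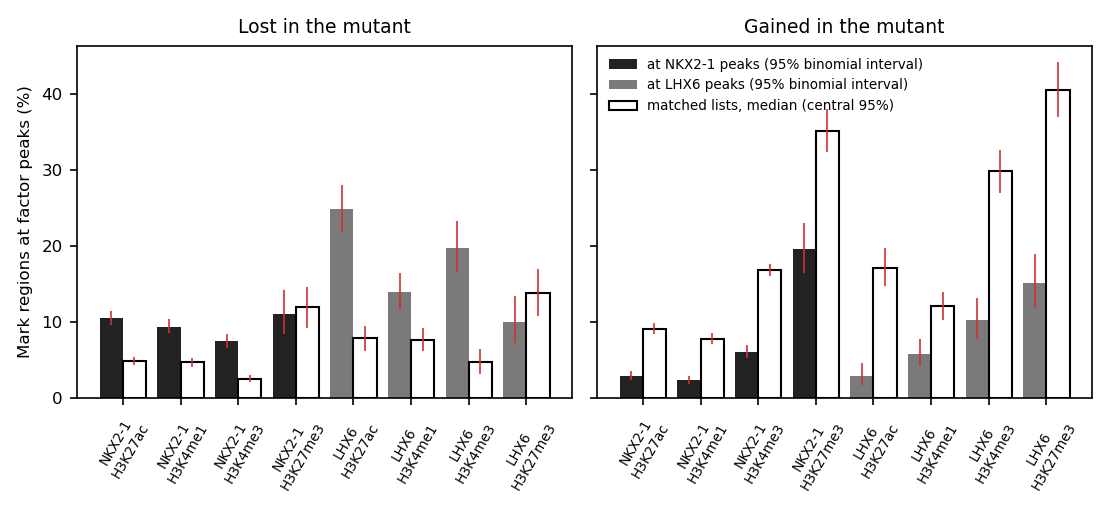
Percent of mark regions at NKX2-1 (black) and LHX6 (grey) peaks that were lost or gained in the mutant, 1 library each, with exact 95% binomial intervals, beside the median and central 95% of 10000 matched lists (white). H3K27ac losses of 10.4% and 24.8% lie above their matched lists, and gains lie below, LHX6 H3K4me3 not so at the same covered length.

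The strongest H3K27ac regions lost with an NKX2-1 peak lay at 70268666 to 70270772 on chromosome 10, nearest to 4930533K18Rik, then in an exon of Thsd7a, and at 118277015 to 118278664 and 118329806 to 118331230 on chromosome 8, 46.4 and 98.8 kb from Maf, with others near Ccdc68 and in introns of Lypd6b, Garnl3 and Adamts12. With an LHX6 peak, regions 122 kb from Cacng3, in an intron of the potassium channel gene Kcnc2, near Rtp4 and in an intron of Tbc1d9 were also lost; these were chosen after their values were seen. Gained with an NKX2-1 peak were H3K27ac regions at 116593249 to 116595167 on chromosome 2, nearest to Tmco5, near Basp1, in introns of Nckap5 and Btbd9, near Prokr2 and Gm2058, and 2 near Wac. H3K27me3 lost with an NKX2-1 peak was strongest in an intron of Iqch, followed by a region at Nkx2-1 inside the unmarked stretch, and further regions near Galnt5, Tmem125, Lmo1, Gm10354, Itln1 and Fam125b. H3K27me3 was gained in Plk1s1, near Rhbg and Tle1, at Rasgef1a, in Atxn7l1, at 3110070M22Rik and at 2 places near Gm15319. In this paragraph near names the gene with the nearest TSS, which could be as far as 368 kb (Galnt5). The distance was 305 kb for Gm2058, 182 kb for Tle1, 129 kb for Basp1 and 126 and 137 kb for Wac.

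At distal NKX2-1 peaks, acetylation was kept more often than lost. Where lost, it gave way to H3K4me1 alone or to no mark, and seldom to H3K27me3. Distal here means without H3K4me3 in either genotype, whatever the distance to a TSS. These counts have no matched lists beside them, and 40.3% of all H3K27ac regions away from H3K4me3 were lost. Of 2002 NKX2-1 peaks with no H3K4me3 in either genotype, 620 had H3K27ac without H3K27me3 in wild type and 386 in the mutant. Of the 620, 348 kept that state, 150 had H3K4me1 alone in the mutant, 117 none of the marks and 3 H3K27me3. H3K27ac was present in wild type alone at 272 peaks and in the mutant alone at 38, and H3K27me3 in wild type alone at 45 and in the mutant alone at 60, an order that the same covered length reversed (154 and 10). Peaks with none of these marks numbered 791 in wild type and 1017 in the mutant. Of 1066 distal LHX6 peaks, 189 had H3K27ac without H3K27me3 in wild type, of which 73 kept it, 52 had H3K4me1 alone, 60 none and 3 H3K27me3. With an overlap of at least 50%, 19 went to H3K4me1 alone and 19 to none.

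Which genes lie near the peaks was asked with the same lists. LHX6 peaks lay within 50 kb of a TSS of 11 of 34 MGE and ventral transcription factors, above the matched lists (median 2, central 95% 0 to 5). NKX2-1 peaks lay near 22 of the 34 (median 17, 12 to 22), inside. The remaining NKX2-1 counts were all inside their matched ranges: 11 of 26 LGE and CGE, 16 of 30 interneuron, 3 of 11 cholinergic, 7 of 13 SHH, 9 of 20 progenitor, 8 of 20 WNT and BMP, 6 of 16 pallial, 3 of 8 oligodendrocyte, 1 of 12 endothelial and blood, 1 of 6 microglial, 4 of 12 lung and thyroid, 0 of 22 Hox and 8 of 16 housekeeping genes. So were the LHX6 counts, at 2, 4, 1, 1, 1, 0, 1, 0, 0, 0, 1, 0 and 0 genes in the same order. Past the range with other windows were MGE genes near NKX2-1 peaks within 20 kb (16), and interneuron (11) and Hox genes (4) near LHX6 peaks within 100 kb. Genes were counted singly, so neighbours such as Dlx1 and Dlx2, Dlx5 and Dlx6 or clustered Hox genes can share a peak.

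Promoter marks within 2.5 kb of a TSS were counted in both genotypes. Over all 22342 genes, H3K27ac was gained at 558 promoters and lost at 131, H3K4me1 at 295 and 326, H3K4me3 at 280 and 23, and H3K27me3 at 783 and 116. At the same covered length losses outnumbered gains for every mark, so the balance rests on the length of the lists. Gbx1 lost H3K27ac and H3K4me1, and Gbx2 lost H3K27ac, while Olig1 and Npas1 gained H3K27ac and Etv1 gained H3K27me3. The striatal genes Drd1, a dopamine receptor gene, and Tac1, a neuropeptide gene, gained H3K27ac, while Htr3a lost H3K4me3 and Adora2a H3K4me1. Of 16 pallial genes, 4 gained H3K27ac: Bhlhe22, Slc17a6 (the vesicular glutamate transporter), Fezf2 and Neurod1, and Neurod6 gained H3K4me3 and lost H3K27me3. Gas1 lost H3K27me3, and Dll1, a Notch ligand gene, Hes5, a Notch target, and Notch2 gained it. Wnt7a, Nog, Cntnap2, Robo1, Tcf4, Mbp, P2ry12 and the housekeeping genes B2m and Tuba1a also gained H3K27me3. Hoxc4, Hoxd8 and Hoxd11 gained H3K4me3, Hoxa5 gained H3K4me1, and Hoxd13, Hoxa10 and Hoxd3 lost it. Calb2, Cldn5, Tmem119 and Sox10 lost H3K4me1, Sox10 lost H3K27ac, Kdr gained H3K27ac, and Cdh5 and Rgs5 gained H3K4me3. The regions behind these changes differed in strength. Those lost at Gbx2 and Hoxd3 (−log10 p 5.12 each) were as weak as any in their wild-type lists. The region gained at Notch2 (5.04) was as weak as any in its mutant list. Olig1 and Npas1 gained regions of 6.37, while the region lost at Gas1 had 62.2. Presence or absence of so weak a region need not mean a large change in the mark.

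Genome-wide, every mutant list was longer. H3K27ac covered 57.0 Mb in wild type and 63.7 Mb in the mutant (mean fold 5.67 and 6.15), H3K4me1 76.5 and 83.8 Mb (4.67 and 4.69), H3K4me3 47.0 and 57.4 Mb (16.9 and 17.8) and H3K27me3 25.7 and 33.7 Mb (5.06 and 5.24). Of wild-type regions, 80.6% of H3K27ac, 84.8% of H3K4me1, 96.4% of H3K4me3 and 84.3% of H3K27me3 overlapped a mutant region. Of mutant regions, 70.4%, 76.2%, 71.9% and 53.4% overlapped a wild-type region. The Jaccard index of the covered bases was 0.641, 0.647, 0.778 and 0.634.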

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

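Of the tests in this part, those on motif cores were chosen only after the result was seen. Regions on contigs outside chromosomes 1 to 19 and X, which no comparison used, exceeded the 3 that a count of 0 allows in all 10 lists. They numbered 185 for NKX2-1 and 222 for LHX6. In wild type they numbered 33 for H3K27ac, 77 for H3K4me1, 164 for H3K4me3 and 256 for H3K27me3, and in the mutant 33, 68, 141 and 259 in the same order. On unplaced sequence lay 154 for NKX2-1, 177 for LHX6 and 225 for wild-type H3K27me3. On unplaced Y sequence there were 16 NKX2-1 and 31 LHX6 regions.

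Some peaks on the main chromosomes were common to all lists. NKX2-1 had 61 and LHX6 62 peaks that overlapped a region in every other list, mark libraries of both genotypes included, with a median −log10 p of 75 and 98.4 against 15.9 and 16 for the other peaks. They lay over Sfi1 (chromosome 11), at 39979772 to 39985942 (17), over Gm10801 (2) and near the start of chromosome 9, and their NK2 core was no more frequent at NKX2-1 summits (23.0%) than to the sides (22.1%).

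A further 504 LHX6 peaks were shared with NKX2-1 yet lay outside wild-type H3K27ac and H3K4me1. Per the labels, factors and marks came from different strains and tissue. A missing mark may reflect that difference, which was not tested. If they were the motif-driven binding seen at marked shared peaks, the LIM core would be as frequent; it lay in 22.4% of them (18.9 to 26.3) against 55.8% (51.1 to 60.5) at marked shared peaks, which argues against that as the whole cause. Repeated sequence may explain part: 21.4% of these windows were repeated in the reference (upper bound 25.3) against 15% of unshared unmarked LHX6 peaks, below the 50% set beforehand, but repeats collapsed in the assembly look unique, which keeps this open. Enrichment common to unrelated antibodies is a candidate explanation too: 35.9% (31.7 to 40.3) overlapped H3K27me3 in both genotypes, against 12.4% of unshared ones, and since the interval holds the 40% set beforehand this cannot be told apart. Binding at part of these peaks stays open, since the LIM core at LHX6 summits was still above the sides (15.6%, 13.4 to 18.0). The NK2 core at NKX2-1 summits of this class lay in 10.9% (8.34 to 13.9), against 15.3% (12.1 to 18.9) at marked shared peaks. Each core was near its sides at the summits of the other factor. The LIM core lay in 18.1% of NKX2-1 summits against 17.7%. The NK2 core lay in 6.94% of LHX6 summits (4.88 to 9.53) against 5.36% (4.05 to 6.93).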

How the results depend on the processing

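The alternatives gave 1124 values for 316 results, and 1010 stayed the same. Tested values were called the same if they kept their side of the threshold and, where either was past it, their direction. A change of direction inside the range thus counted as the same. For example, NKX2-1 peaks lay near 1 of 12 endothelial and blood genes within 50 kb (median 3) and near 7 within 100 kb (median 5). Counts without a test were called the same within a factor of 1.5, and the overlap between genotypes within the exact 95% interval. Of tested values 3 reversed, and 98 untested ones moved past these limits. Called the same were 129 of 134 for losses and gains at factor peaks, 336 of 344 for coverage around genes, 109 of 112 for gene lists near peaks, 16 of 16 for motif cores, 0 of 16 for the overlap between genotypes (the order of the genotypes held at −log10 p of at least 10 and turned at the same covered length), and 420 of 502 for the remaining results. Those named below as added were chosen after seeing the data. No paired analysis was possible because only input libraries share replicate numbers between genotypes, and they enter no test. With 1 library per group, no alternative tests replicate error.

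With both genotypes at the same covered length, the weakest mutant regions were removed, which by construction raises losses and lowers gains. H3K27me3 losses then lay above matched lists by 10.5 points at NKX2-1 and by 11 points at LHX6 sites, both reversed, and H3K4me3 gains at LHX6 sites were −0.922 points, inside the range. Shared wild-type and mutant regions became 71.6% and 81.4% for H3K27ac, 77.1% and 83.4% for H3K4me1, 73.7% and 99.3% for H3K4me3, and 61.0% and 87.5% for H3K27me3. Distal NKX2-1 peaks with H3K27me3 numbered 10 in the mutant alone and 154 in wild type alone. Promoters gained and lost became 289 and 310 for H3K27ac, 169 and 689 for H3K4me1, 16 and 341 for H3K4me3, and 84 and 795 for H3K27me3. Pallial genes in the higher H3K27ac tail rose to 2, past the range, MGE genes in the lower H3K4me1 tail fell to 5 and SHH genes in the higher H3K4me3 tail to 2, both inside.

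At −log10 p of at least 10, shared wild-type and mutant regions were 83.9% and 71.1% for H3K27ac, 83.1% and 76.8% for H3K4me1, 97% and 74.1% for H3K4me3, and 86.8% and 58.5% for H3K27me3. H3K27me3 in wild type alone fell to 26 distal NKX2-1 peaks. At LHX6 sites (added) H3K27me3 losses were −2.89 points from matched lists, inside the range. Counting regions within 1 kb moved H3K27me3 losses at NKX2-1 sites to 1.69 points above matched lists, reversed, and 5 distal peaks went from H3K27ac to H3K27me3. With an overlap of at least 50%, 6 did, and 75 had H3K27ac in the mutant alone. Distal LHX6 peaks then had H3K27ac in wild type alone at 44 and in the mutant alone at 25 (118 and 13 before), 19 went to H3K4me1 alone and 19 to none, and H3K27ac losses at LHX6 sites were 12.3%, 7.31 points above matched lists, still outside. The causes were not tested.

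Within 20 kb, NKX2-1 peaks lay near 16 MGE genes, past the range; within 100 kb, LHX6 peaks lay near 11 interneuron and 4 Hox genes, both past it. Within 25 kb of the TSSs (added), 2 MGE and 2 cholinergic genes were in the lower H3K4me1 tail, inside the range. Without Nkx2-1 (added) the MGE count was 5. With finer matching (added), 4 LGE and CGE genes in the lower H3K27me3 tail fell inside the range and 0 Hox genes in the higher one lay below it. The causes were not tested. The depth of the H3K4me3 libraries (28.8 and 26.8 M tags) limits what a missing H3K4me3 region means.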

Other observations

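The tests on the patterns in this part were chosen only after the result was seen, though −log10 p of at least 10 at NKX2-1 sites was a setting fixed beforehand, and the genes of the next 2 paragraphs were chosen after their values were seen. Outside the fixed lists, the strongest falls of H3K27ac after Tcf4 were at Cux1, a homeobox gene (32.7 kb in wild type, 11.5 kb in the mutant), Tiam1, a Rac activator gene (34.0 and 18.1 kb), and Tox2 (36.8 and 21.9 kb). Among the strongest rises were those at 1700112E06Rik (5.16 and 42.8 kb), Auts2, a neurodevelopmental gene (56 and 93.3 kb), and Zbtb20 (40.4 and 61.5 kb). Kcnma1, a potassium channel gene, had H3K27ac of 1.92 and 18.9 kb and H3K27me3 of 26.1 and 9.37 kb.

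H3K27me3 rose at Fgfr2, a growth factor receptor gene (177 and 245 kb), Dab1, the Reelin adaptor gene (20.5 and 41.5 kb), and Plagl1, an imprinted gene (0.942 and 17.0 kb). On the X chromosome it rose at Tsc22d3 (16.1 and 35.0 kb) and Bcor, a Polycomb co-repressor gene (19.6 and 33.3 kb). X as a whole held 279 kb of H3K27me3 in wild type and 631 kb in the mutant (mean fold 4.43 and 4.24), a ratio of 2.26, where the autosomes ranged from 1.16 to 1.5. At −log10 p of at least 10 the ratio was 1.97 (autosomes 1.16 to 1.52), and at the same covered length 1.21 (0.930 to 1.13). The sex of the embryos is not given in the sources used here.

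H3K27ac was lost at NKX2-1 sites more often than at matched regions. A shorter or weaker mutant list was argued against, since the mutant list is longer and the excess was 5.48 points at −log10 p of at least 10. Absence of LHX6 from sites with a called LHX6 peak was argued against as the whole cause, since NKX2-1 sites without one showed an excess of 4.53 points. LHX6 peaks came from 1 library of 50.7 M tags. Loss of LHX6 binding too weak to be called was not tested. Choice of sites in wild-type tissue may contribute. The loss was 2.26 times the matched share at sites with the NK2 core (1.89 to 2.67) and 2.19 times at sites without it (1.97 to 2.42). These ratios are alike, as this explanation needs. In points the excess was 8.05 with the core and 5.25 without it. The shares lost were 14.5% (12.1 to 17.1) and 9.69% (8.73 to 10.7). The scale was chosen after the result was seen, so this comparison cannot decide. A direct effect of NKX2-1 binding stays open as a hypothesis, beside the choice of sites and a loss of uncalled LHX6 binding.

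Coverage of H3K27ac, H3K4me1 and H3K4me3 was lower at part of the MGE genes and higher at part of the LGE and CGE genes. A longer mutant list was argued against, with 13 LGE and CGE genes in the higher H3K27ac tail (upper bound 4) and 8 MGE genes in the lower one (upper bound 5) at the same covered length. Full replacement of MGE by LGE tissue was argued against, since Nkx2-1 kept 117% of its H3K27ac coverage outside the unmarked stretch. That stretch was picked for having no mutant region, which raises this share. Over the whole window H3K27ac covered 12.6 kb in wild type and 9.56 kb in the mutant. A rise of every other cell type as MGE cells fell cannot be told apart. Of 29 acetylated pallial, oligodendrocyte, endothelial and microglial genes, 3.45% were in the higher H3K27ac tail (0.0873 to 17.8). Of LGE and CGE genes 52.2% were (30.6 to 73.2). But pallial genes passed their range for H3K4me3, and for H3K27ac at the same covered length (2 genes). Of pallial promoters 25% gained H3K27ac, against 2.5% of all. A promoter can gain only where wild type has no region, and this contrast was not matched on that. Partial admixture of LGE tissue and a change of mutant MGE cells towards LGE or CGE chromatin were not tested and stay open.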
